A study of Mus musculus with 6 samples.

How the data were processed

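Whole ovaries of female C57BL/6J mice were profiled by RNA sequencing after housing at the local pressure of Lanzhou or in a chamber that held the low pressure and low oxygen of high altitude. The 6 libraries formed 2 groups of 3, normal pressure and hypobaric hypoxia, and the group and replicate number of each were taken from the sample titles. The labels conflict on several points. The hypoxia altitude is 6500 m in the titles, treatment fields and series text (43.12 kPa, with an oxygen pressure of 8.1 kPa in the treatment fields) but 5000 m in the descriptions. The control altitude is 1500 m in the titles and 1588 m in the series text (83.56 kPa, with 17.8 kPa oxygen in the treatment fields). Exposure lasted 15 days in the series text, whereas the descriptions of replicates 1, 2 and 3 give 15, 16 and 17 days. The light and dark hours of the 3 control samples read 12 and 12, 12 and 13, and 12 and 14. The age is 8 weeks in the series text and 6 to 8 weeks in the descriptions. Before exposure, cycles were synchronised by gavage of levonorgestrel and ethinylestradiol per the labels, which give doses of 0.1 and 0.02 mg/kg for the hypoxia samples only. Each group held 15 mice. Which mouse or pool of mice gave each library is not stated in the labels, so p-values measure only the spread between these libraries, which may be partly technical. All 6 samples carry batch 1.

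Per the labels, total RNA was extracted with a column kit and made into libraries with a SMARTer mRNA kit. The submitters' processing notes name HISAT2, Bowtie2 and DESeq2, without versions or roles, and the genome build GRCm38.p6. The read counter, the gene annotation and any filter are not given in the sources used here. The authors deposited 1 table of TPM values with 33036 features and 1 column per library. TPM, a measure of transcript abundance, divides reads by transcript length and scales each library to a fixed total, and the deposited columns summed to between 998175 and 998954. Messenger, long noncoding and small structural RNAs share that total, so a change in a few abundant features shifts the values of all others. The 20 most abundant features held 44.5% to 52.6% of TPM. The single feature Zfp949 held 14.5% to 16.3% in the normal-pressure libraries and 10.2% to 13.7% in the hypoxia libraries. Protein-coding genes other than Zfp949 held 37.3% in normal-pressure replicate 2 and 42.2% to 45.7% in the other libraries. TPM keeps no read depth, so the depth of each library is unknown and no counting interval is given. An exact 0 can be a failed estimate in such a table, and features at 0 are reported as listed at 0. Of the features, 25485 matched a symbol in the RefSeq gene table of GRCm38.p6, which also gave gene types and coordinates, 6215 were RNAcentral identifiers and 1336 were unmatched. Among all features, 26 have a date in place of a symbol and are not named. No mitochondrially encoded gene was among the features used here.

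The test was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(TPM + 1), hypobaric hypoxia minus normal pressure, with no covariate. Features with TPM of at least 1 in at least 3 libraries were kept, which left 17120, of which 13796 were protein coding, 1616 were long noncoding RNAs and 1143 were RNAcentral identifiers. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05, two-sided. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values, and errors are limma's moderated standard errors (SE). Values in TPM are means ± SD with n = 3 per group.

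The design, the gene lists, the rule for named genes and the alternatives, except those said to be added, were fixed before the data were examined. The 36 lists covered HIF targets and glycolysis, steroidogenesis, cholesterol synthesis, ovulation and cumulus expansion, cell cycle, replication-dependent histones, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, antioxidant and NRF2 targets, the unfolded protein and integrated stress response, heat shock, immediate early, glucocorticoid-responsive, circadian clock, apoptosis and p53, autophagy and mitophagy, extracellular matrix, inflammatory cytokine, interferon-stimulated, cytosolic ribosomal protein and annotated long noncoding RNA genes. Marker lists covered granulosa, oocyte, luteal, theca and interstitial cells, oviduct and ovarian surface epithelium, adipose tissue, erythroid cells, endothelium, smooth muscle and pericytes, skeletal muscle, macrophages, lymphocytes and neutrophils. The 32 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Named genes were the 10 highest and 10 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 TPM in the higher group and groups that did not overlap, and the 3 highest and 3 lowest noncoding genes with a mean of at least 1 TPM. Clone and predicted-model names were skipped (3 higher and 1 lower). From each list, all called members were named if there were 6 or fewer and otherwise the 4 of smallest p, and where none was called the 2 of smallest p. Some genes that this rule names are not reported here. Other genes named here were chosen after their values were seen, and that holds for Parm1, Timp3, Pgr, Ptx3, Prlr, Star, Alas2, Bpgm, Ndrg1, Ccn2, Tsc22d3, S100a9, Zfp949 and Snord15b.

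On simulated data with the 17120 genes and 200 planted changes, the pipeline recovered 95% of the 100 changes of 2-fold and 55% of the 100 changes of 1.5-fold, with 5 false calls (3.23% of calls). It made 0 gene calls and 0 list calls when no change was planted. The simulated genes were independent, so this does not test lists of correlated genes. Changes were planted only in genes above about 5 TPM at normal pressure, so recovery at lower values was not tested. Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 TPM, quantile normalization, median-ratio scaling, removal of haemoglobin genes, robust variance, the replicate number as a block, an adjusted p of 0.1 and leaving out each library in turn. Scaling to the protein-coding total without Zfp949, protein-coding genes alone and features above 0 in every library were added after the data were seen.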

Results

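RNA sequencing of whole mouse ovary gave 6 libraries, 3 from mice kept at normal pressure and 3 from mice kept under hypobaric hypoxia at a simulated 6500 m. Each library is described by TPM values for 33036 features, and its read depth is unknown. Between 27809 and 29402 features were above 0, with 3634 to 3751 listed at 0 in the normal-pressure libraries and 4753 to 5227 in the hypoxia libraries. Pearson correlations of log2(TPM + 1) across genes were 0.992 between normal-pressure libraries, 0.977 to 0.983 between hypoxia libraries and 0.958 to 0.977 across groups. The first principal component held 55.0% of the variance and separated the groups, with hypoxia replicate 3 (12.4) nearer to the normal-pressure libraries (-26.9 to -24.4) than hypoxia replicates 1 (29.8) and 2 (34.5).

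The comparison asked which ovarian transcripts differ after exposure to the low pressure of high altitude. Most tested genes of the corpus luteum, of steroid and cholesterol synthesis and of fat tissue were lower under hypoxia, and most haemoglobin, oocyte and cell division genes were higher. This rests on counts of single genes, since no list call held with an estimated correlation. The values are of whole ovary, so a change within cells and a change in the mix of cells cannot be told apart. Fat or oviduct left on at dissection was not assessed. Hormone doses are labelled for the hypoxia samples only, so hypoxia and hormone treatment cannot be told apart if the controls were not dosed. The steepest falls among protein-coding genes were in Akr1c18, an enzyme that inactivates progesterone, and Sfrp4, a secreted Wnt antagonist, at log2 fold changes of -4.38 (SE 0.78) and -3.95 (SE 0.73). The highest rises were in the haemoglobin genes Hba-a2, Hba-a1, Hbb-bs and Hbb-bt, between 5.87-fold and 6.50-fold. Of 17120 features tested with limma, 3139 changed, with 1906 higher and 1233 lower, and 2596 of them were protein coding (1522 higher and 1074 lower). Of the 306 that changed at least 2-fold, 63 were higher and 243 lower. At an unadjusted p under 0.05 there were 5482, where chance gives 856, and the groups did not overlap for 6712 features, 39.2% of those tested where chance gives 10%. The median log2 fold change of all tested features was 0.08. The direction split depended on scaling, with 60.7% of calls higher in TPM as deposited and 46.0% with median-ratio scaling (2735 higher and 3205 lower). Leaving out normal-pressure replicate 2 gave 46.4% (1855 higher and 2143 lower), and 795 were lower without normal-pressure replicate 3, 1239 were higher without hypoxia replicate 1, and 2065 changed, 1170 of them higher, without hypoxia replicate 2.

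Luteal markers fell as a group. Of 15 tested members 13 fell and none rose, 13 also when adjusted over the list alone, with a median log2 fold change of -1.83 (camera adjusted p = 6.62e-19, and adjusted p = 0.39 with an estimated correlation). Abcb1b, which encodes an efflux transporter, fell from 96.6 ± 10.4 to 10.5 ± 6.89 TPM (log2 fold change -3.25, SE 0.27, adjusted p = 2.28e-06). Ptgfr, the receptor for the luteolytic prostaglandin F, fell from 72.6 ± 32.9 to 5.89 ± 4.20 TPM (adjusted p = 1.39e-05), and Gpx3, a secreted glutathione peroxidase, from 453 ± 105 to 148 ± 22.1 TPM (adjusted p = 8.5e-06). Sfrp4 fell from 417 ± 229 to 43.7 ± 38.1 TPM. Its hypoxia replicates 1 to 3 measured 78.0, 2.67 and 50.5 TPM, so the size of its log2 fold change rests partly on replicate 2. Akr1c18 measured 54.6, 43.6 and 474 TPM in the normal-pressure libraries and 22.2, 1.03 and 1.80 TPM in the hypoxia libraries, so its group mean rests largely on normal-pressure replicate 3. With robust variance Akr1c18, Sfrp4, Hsd17b7 and Star no longer passed and 9 members fell, and Sfrp4 did not pass without normal-pressure replicate 2. The falls numbered 9 with no filter, 12 without normal-pressure replicate 3 and 14 with quantile, median-ratio or protein-coding total scaling. Parm1 (22.1 ± 4.94 and 21.0 ± 2.03 TPM) and Timp3 (55.1 ± 8.31 and 47.1 ± 2.36 TPM) did not pass the test.

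The steroidogenesis list shares 8 tested members with the luteal list. Of its 20 tested members 12 fell and none rose over all genes, while adjusted over the list alone 12 fell and 4 rose. The median was -0.65 (camera adjusted p = 7.04e-08, and adjusted p = 0.46 with an estimated correlation). Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, fell from 2607 ± 432 to 688 ± 202 TPM (log2 fold change -1.95, SE 0.20, adjusted p = 1.2e-05). Its electron donor Fdx1 fell from 442 ± 99.8 to 151 ± 33.0 TPM, the luteinizing hormone receptor Lhcgr from 85.3 ± 24.0 to 23.1 ± 10.2 TPM, Hsd17b7 from 73.8 ± 4.33 to 14.1 ± 10.9 TPM, and Star, which carries cholesterol into mitochondria, from 167 ± 24.1 to 52.2 ± 33.8 TPM. Quantile normalization and protein-coding total scaling each called 5 members higher, median-ratio scaling 3, and 2 rose without normal-pressure replicate 3. With robust variance 8 fell and 1 rose, and Star and Hsd17b7 were among those lost. With no filter 8 of 21 tested members fell, and Star did not pass. The cholesterol synthesis list had 21 of 23 tested members lower and none higher, 22 lower when adjusted over the list alone. The median was -0.78 (camera adjusted p = 2.99e-21, and adjusted p = 0.46 with an estimated correlation). Hmgcs1, at the start of the mevalonate pathway, fell by 1.26 on the log2 scale (117.8 ± 28.9 to 47.9 ± 5.28 TPM), Mvd by 1.32, Fdps by 1.19 and Dhcr7, which makes cholesterol from its last precursor, by 1.48. With no filter on low values 9 of these members passed.

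**Figure D1:**
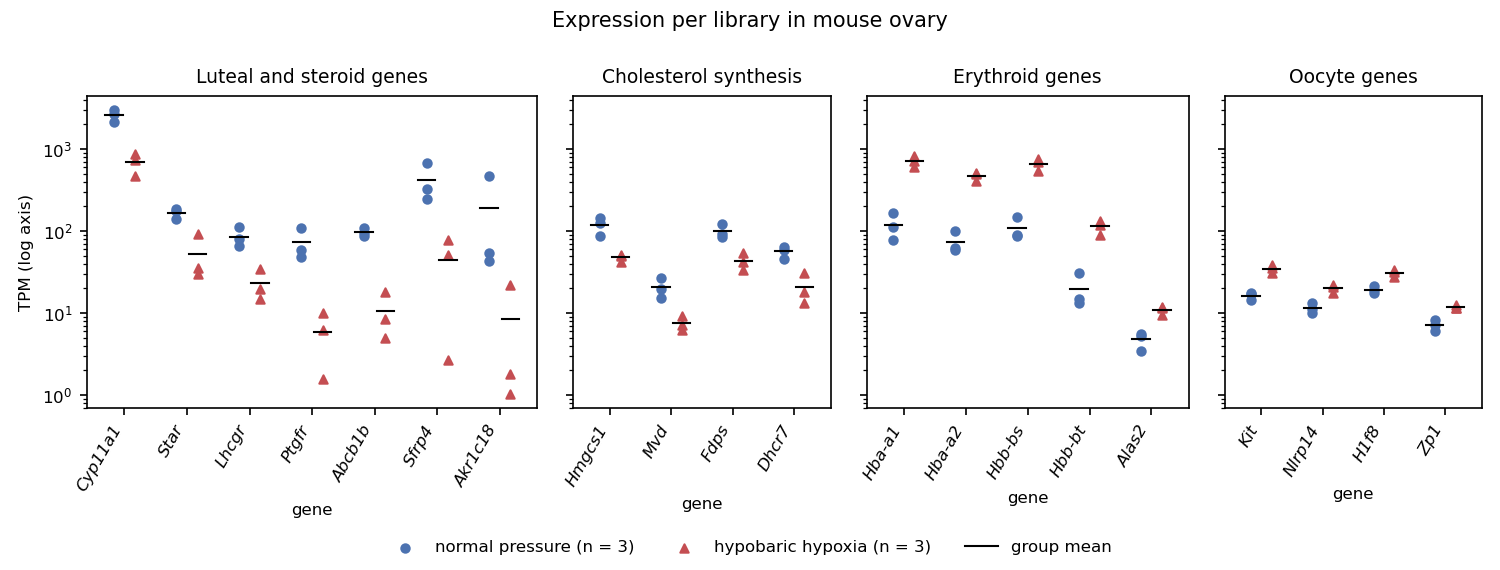
TPM per library on a log axis for luteal and steroid, cholesterol synthesis, erythroid and oocyte genes, with 3 normal-pressure libraries as circles, 3 hypoxia libraries as triangles and group means as lines. The groups do not overlap for the genes drawn, and Akr1c18 shows 1 normal-pressure library at 474 TPM, 2 at 54.6 and 43.6 TPM and its highest hypoxia library at 22.2 TPM.

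All 7 tested erythroid markers rose, 7 also when adjusted over the list alone. The median was 2.55 (camera adjusted p = 3.47e-10, and adjusted p = 0.39 with an estimated correlation), the value of Hbb-bt, since 4 of the 7 are haemoglobin genes. With no filter 6 of 11 members rose, and the median was then lower and no longer fell on a haemoglobin gene. Hba-a1 (GRCm38.p6 chromosome 11, 32283672 to 32284486) rose from 118 ± 43.8 to 716 ± 103 TPM and its neighbour Hba-a2 (chromosome 11, 32296492 to 32297310) from 73.9 ± 22.2 to 475 ± 55.0 TPM. On chromosome 7, Hbb-bs (103826523 to 103827928) rose from 108 ± 34.1 to 666 ± 113 TPM and Hbb-bt (103812524 to 103813923) from 19.6 ± 9.51 to 114 ± 22.3 TPM. Limma's adjusted p for these 4 genes lay between 8.69e-08 and 3.25e-06. The 2 alpha and the 2 beta genes are near-identical pairs, so the division of reads within each pair is uncertain. Haemoglobin genes together held 0.0242% to 0.0443% of TPM in normal-pressure libraries and 0.166% to 0.223% in hypoxia libraries.

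Oocyte markers rose together, with 21 of 23 tested members higher and none lower, and 22 higher when adjusted over the list alone. The median was 0.63 (camera adjusted p = 1.65e-11, and adjusted p = 0.46 with an estimated correlation). Kit, the receptor for Kit ligand, rose from 16.2 ± 1.70 to 34.8 ± 3.77 TPM (adjusted p = 2.7e-05), Nlrp14 from 11.4 ± 1.64 to 20.1 ± 2.40 TPM, the oocyte linker histone H1f8 from 19.2 ± 1.84 to 30.8 ± 3.04 TPM and the zona pellucida gene Zp1 from 7.04 ± 1.08 to 11.9 ± 0.604 TPM. With no filter 10 members passed. Cell cycle genes followed the same direction, with 22 of 30 members higher and none lower, and 25 higher when adjusted over the list alone. The median was 0.46 (camera adjusted p = 2.35e-10, and adjusted p = 0.50 with an estimated correlation). The replication helicase subunits Mcm6 and Mcm2 rose by 0.70 and 0.51, the proliferation marker Mki67 by 0.69 and the spindle checkpoint kinase Bub1b by 0.57 on the log2 scale. The number of cell cycle genes that passed was 13 without hypoxia replicate 2 and 7 with no filter.

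Granulosa cell markers moved both ways, with 6 of 21 higher and 3 lower, and 9 higher and 5 lower when adjusted over the list alone (median 0.21, camera adjusted p = 0.36). The estrogen receptor gene Esr2 rose from 86.9 ± 7.52 to 200.4 ± 8.34 TPM (log2 fold change 1.20, SE 0.11, adjusted p = 4.8e-06), the activin antagonist Fst from 41.9 ± 2.59 to 68.7 ± 8.26 TPM and the hedgehog ligand Ihh from 20.5 ± 1.43 to 31.0 ± 2.70 TPM. The aromatase gene Cyp19a1 fell from 18.9 ± 5.38 to 4.42 ± 3.05 TPM. The lower count was 6 with quantile or median-ratio scaling and 5 with protein-coding total scaling or without normal-pressure replicate 2, and 1 without normal-pressure replicate 1 or hypoxia replicate 2, and Cyp19a1 did not pass with robust variance. The median was 0.11 with median-ratio scaling. Among 13 theca and interstitial markers 4 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone (median 0.29, camera adjusted p = 0.40). Insl3, a peptide hormone of theca cells, rose from 10.5 ± 3.69 to 41.9 ± 11.0 TPM (adjusted p = 1.36e-05), and the hedgehog targets Ptch1 and Gli1 and the aminopeptidase gene Enpep rose by 0.63, 0.51 and 0.42. Mgarp fell by 1.03 and Cyp11a1, counted in this list too, fell as above. The rise of Enpep did not pass without hypoxia replicate 1 or 2, and 2 theca markers rose with no filter. In the ovulation and cumulus expansion list 7 of 11 fell and 1, Ptx3, rose, also when adjusted over the list alone. Ptx3 did not reach the filter, and so was not tested, without any 1 hypoxia library or with a minimum of 5 TPM, nor was Edn2 without any 1 normal-pressure library or with that minimum. The median was -0.44 (camera adjusted p = 9.75e-06, and adjusted p = 0.46 with an estimated correlation). The protease gene Adamts1 fell from 22.3 ± 3.96 to 8.36 ± 1.15 TPM, the transcription factor gene Runx2 from 44.4 ± 13.5 to 8.03 ± 5.24 TPM, the endothelin gene Edn2 from 2.33 ± 0.838 to 0.617 ± 0.181 TPM, and Sphk1 and the progesterone receptor gene Pgr by 0.62 and 0.85 on the log2 scale. Runx2 did not pass with robust variance, and 4 of the list's falls passed with no filter, where the median was -0.28. Ptx3 and Pgr did not pass with no filter.

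Among genes that hypoxia-inducible factors are known to raise, those that changed were mostly lower. These are whole-ovary values, so lower expression within cells and a smaller share of cells that express these genes cannot be told apart here. Of 31 HIF target and glycolysis genes 12 fell and 2 rose, and 16 fell and 2 rose when adjusted over the list alone. The median was -0.29 (camera adjusted p = 4.2e-06, and adjusted p = 0.50 with an estimated correlation). Bnip3, a mitophagy receptor gene, fell from 37.6 ± 2.17 to 23.5 ± 0.532 TPM (adjusted p = 0.000488), the lactate exporter gene Slc16a3 from 7.66 ± 0.731 to 4.67 ± 0.556 TPM and Angptl4 from 40.0 ± 5.01 to 26.5 ± 2.45 TPM. The collagen prolyl hydroxylase gene P4ha1 rose from 19.7 ± 1.21 to 29.4 ± 3.51 TPM and Ndrg1 rose by 0.38. The count of falls was 22 with median-ratio scaling, 21 with quantile normalization, 20 with protein-coding total scaling, 6 without normal-pressure replicate 1, 5 without hypoxia replicate 2 and 4 with no filter, and the rises numbered 4 with quantile normalization and 5 with protein-coding total scaling. Ndrg1 did not pass without any 1 hypoxia library or with no filter. Of 33 nuclear-encoded oxidative phosphorylation genes 5 fell and none rose, also when adjusted over the list alone. The median was -0.21 (camera adjusted p = 5.79e-09, and adjusted p = 0.50 with an estimated correlation). The respiratory chain genes Ndufa4, Sdhb, Cox5b, Cox6a1 and Uqcrb fell by 0.64, 0.50, 0.51, 0.38 and 0.37 on the log2 scale. This count was 31 with median-ratio scaling, 28 with protein-coding total scaling, 23 with quantile normalization, 25 without normal-pressure replicate 2, 3 without any 1 of the other 5 libraries, 3 with no filter and 9 among protein-coding genes alone. Cox6a1 and Uqcrb did not pass without any 1 library except normal-pressure replicate 2. Fatty acid oxidation genes gave 4 falls and 1 rise among 16, also when adjusted over the list alone. The median was -0.19 (camera adjusted p = 0.00228, and adjusted p = 0.50 with an estimated correlation). Acaa2, Slc25a20, Cpt1a and Cpt2 fell by 0.52, 0.43, 0.46 and 0.43, and Ppara rose by 0.45. Ppara was lost without normal-pressure replicate 2 or 3 or hypoxia replicate 1, Cpt2 without normal-pressure replicate 1 or 3, Slc25a20 without normal-pressure replicate 1 or hypoxia replicate 2, and Cpt1a without hypoxia replicate 2. The list's camera adjusted p was 0.064, 0.069 and 0.12 without hypoxia replicates 1, 2 and 3 and 0.053 among protein-coding genes alone, within a range of 0.000204 to 0.50 over the alternatives. The falls numbered 9 with quantile, median-ratio or protein-coding total scaling, 8 without normal-pressure replicate 2, and 2 without normal-pressure replicate 1, without hypoxia replicate 2 or with no filter.

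Antioxidant and NRF2 target genes gave 6 falls and 1 rise among 21, and 8 falls and 2 rises when adjusted over the list alone. The median was -0.18 (camera adjusted p = 7.65e-05, and adjusted p = 0.50 with an estimated correlation). The glutathione peroxidase gene Gpx1 fell from 193 ± 8.54 to 110.4 ± 5.44 TPM, Srxn1 and Gsta4 fell by 0.89 and 0.63, and the heme oxygenase gene Hmox1 rose from 38.5 ± 4.53 to 51.0 ± 4.09 TPM. The falls numbered 14, 13 and 12 with median-ratio, quantile and protein-coding total scaling, 12 without normal-pressure replicate 2, 3 without normal-pressure replicate 1 or hypoxia replicate 1 or 3, and 1 with no filter. The median was -0.27 with median-ratio scaling, and Hmox1 did not pass without hypoxia replicate 1 or 3. Of 14 glucocorticoid-responsive genes 9 fell and 1, Tsc22d3, rose, and 9 fell and 2 rose when adjusted over the list alone. The rise of Tsc22d3 was lost at a pseudocount of 0.1, with no filter and without any 1 library except normal-pressure replicate 2, and 2 members rose with quantile, median-ratio or protein-coding total scaling. The median was -0.74 (camera adjusted p = 1.08e-07, and adjusted p = 0.46 with an estimated correlation). The kinase gene Sgk1 fell from 86.8 ± 20.3 to 19.0 ± 8.28 TPM (adjusted p = 2.4e-05), the glucocorticoid receptor cochaperone gene Fkbp5 from 176 ± 29.7 to 94.9 ± 8.59 TPM, the metallothionein gene Mt2 from 162 ± 10.1 to 86.3 ± 15.9 TPM and Gpd1 by 1.06. With no filter 5 of these falls passed. Among 14 immediate early genes 4 fell and none rose, and 5 fell and 1 rose when adjusted over the list alone. The median was -0.30 (camera adjusted p = 0.00101, and adjusted p = 0.54 with an estimated correlation). Ier3, Dusp1, Klf4 and Junb fell by 0.86, 1.00, 0.47 and 0.50, and the count was 7 without hypoxia replicate 3 and among protein-coding genes alone and 1 with no filter. The median was -0.47 without normal-pressure replicate 2, -0.19 without normal-pressure replicate 3 and -0.15 without hypoxia replicate 2. Dusp1 did not pass with robust variance, Junb without normal-pressure replicate 1 or 3, and Klf4 without hypoxia replicate 2. Of 13 heat shock genes 4 rose and none fell, also when adjusted over the list alone. The median was 0.23 (camera adjusted p = 0.0292, and adjusted p = 0.69 with an estimated correlation). The chaperone genes Hsph1, Hsp90aa1, Hspa4l and Hspa8 rose by 0.99, 0.66, 0.58 and 0.57, with 2 past the test with no filter and Hspa8 lost without hypoxia replicate 1. The list's camera adjusted p was 0.057, 0.12 and 0.16 without normal-pressure replicates 1 and 2 and hypoxia replicate 1, and 0.056, 0.11 and 0.10 with quantile, median-ratio and protein-coding total scaling, within a range of 0.00618 to 0.69 over the alternatives. Its median was 0.15 without normal-pressure replicate 2, 0.13 without hypoxia replicate 1 and 0.14 with median-ratio scaling.

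Adipose markers fell, with 13 of 15 lower and none higher, and 14 lower when adjusted over the list alone. The median was -0.81 (camera adjusted p = 4.58e-12, and adjusted p = 0.39 with an estimated correlation). The lipid droplet gene Plin4 fell from 61.6 ± 23.5 to 10.8 ± 6.29 TPM, the adipsin gene Cfd from 134.5 ± 12.7 to 51.1 ± 21.3 TPM, Slc36a2 by 0.81 and Dgat2 by 0.76. The count was 7 without normal-pressure replicate 2 and 3 with no filter. Among 16 oviduct epithelium markers 3 fell and none rose, also when adjusted over the list alone (median -0.15, camera adjusted p = 0.00091, and adjusted p = 0.57 with an estimated correlation), namely the oviductal glycoprotein gene Ovgp1 (585 ± 127 to 294 ± 104 TPM) and the cilia genes Cfap126 and Rsph1. Without hypoxia replicate 2 the median was 0.01 and the camera adjusted p 0.26, within a range of 0.000584 to 0.57 over the alternatives, the count was 6 without hypoxia replicate 3 and 5 among protein-coding genes alone and 1 with no filter. The median was -0.25 without normal-pressure replicate 2 or hypoxia replicate 3 and -0.23 with median-ratio scaling, and Ovgp1 did not pass with robust variance. Fat and oviduct left on the ovaries at dissection were not assessed, so the adipose and oviduct falls may not be changes in ovarian cells. Among 11 ovarian surface epithelium markers the keratin genes Krt8, Krt7 and Krt19 fell by 0.43, 0.39 and 0.45 and none rose, and 4 fell when adjusted over the list alone. The median was -0.27 (camera adjusted p = 0.029, and adjusted p = 0.57 with an estimated correlation). This call was lost without any 1 library except normal-pressure replicate 3, and with no filter, quantile, median-ratio or protein-coding total scaling or protein-coding genes alone (camera adjusted p from 0.00615 to 0.57 over the alternatives). The falls numbered 6 with quantile or median-ratio scaling, 5 with robust variance, protein-coding genes alone or without hypoxia replicate 3, 1 without normal-pressure replicate 3 and 0 with no filter or without hypoxia replicate 2, and 1 other member rose without normal-pressure replicate 1 or hypoxia replicate 1. The median was -0.42 without normal-pressure replicate 2, -0.12 without normal-pressure replicate 3 and -0.17 without hypoxia replicate 2. Krt7 was also lost without normal-pressure replicate 1 or hypoxia replicate 1 and Krt19 without normal-pressure replicate 2.

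Extracellular matrix genes gave 11 falls and 2 rises among 25, and 16 falls and 2 rises when adjusted over the list alone. The median was -0.30 (camera adjusted p = 6.24e-07, and adjusted p = 0.50 with an estimated correlation). Lum fell from 47.5 ± 2.35 to 24.0 ± 2.23 TPM, Postn from 17.4 ± 1.00 to 6.00 ± 1.85 TPM and the metalloproteinase inhibitor gene Timp1 from 88.8 ± 33.5 to 19.0 ± 9.33 TPM. Thbs1 rose from 147 ± 13.1 to 325 ± 27.7 TPM and Ccn2 by 0.46. The falls numbered 18 with median-ratio scaling, 17 with quantile or protein-coding total scaling, and 6 without hypoxia replicate 2 or with no filter, and Ccn2 was lost in both of these. Of 13 smooth muscle and pericyte markers 4 fell and 1 rose, and 5 fell and 1 rose when adjusted over the list alone. The median was -0.21 (camera adjusted p = 0.00184, and adjusted p = 0.50 with an estimated correlation). The contractile and filament genes Des, Cnn1, Actg2 and Tagln fell by 1.41, 1.01, 0.93 and 0.62, and the pericyte receptor gene Pdgfrb rose by 0.39, a call lost without any 1 library except normal-pressure replicate 3. The falls numbered 8 with median-ratio scaling and 7 with quantile normalization, and the median was -0.14 without normal-pressure replicate 1. Among 20 endothelial genes 3 rose and 2 fell, and 4 rose and 2 fell when adjusted over the list alone (median 0.14, camera adjusted p = 0.38). Angpt2, Vwf and Cldn5 rose by 0.66, 0.60 and 0.35. The apelin gene Apln fell from 8.30 ± 2.16 to 2.20 ± 0.212 TPM, and Vegfa fell from 41.7 ± 7.10 to 30.9 ± 3.33 TPM. Vegfa did not pass without normal-pressure replicate 1 or 3 or hypoxia replicate 2, and Cldn5 did not pass without normal-pressure replicate 1 or any 1 hypoxia library. In this list 9 members rose with protein-coding total scaling, 5 with quantile normalization and 5 without normal-pressure replicate 3, and the median ran from 0.05 with median-ratio scaling to 0.24 without normal-pressure replicate 3.

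Interferon-stimulated genes fell in 9 of 18 members and none rose, and 11 fell when adjusted over the list alone. The median was -0.37 (camera adjusted p = 8.32e-08, and adjusted p = 0.50 with an estimated correlation). Zbp1, Irf7, Bst2 and Oas1a fell by 0.77, 0.67, 0.55 and 0.54 on the log2 scale. The count was 15 with median-ratio scaling, 14 with quantile normalization, 5 with a minimum of 5 TPM, 4 without normal-pressure replicate 3 or hypoxia replicate 2 and 1 with no filter. Of 12 inflammatory genes 5 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone. The median was -0.29 (camera adjusted p = 0.00218, and adjusted p = 0.50 with an estimated correlation). The nitric oxide synthase gene Nos2 rose from 14.2 ± 0.421 to 36.1 ± 4.41 TPM (adjusted p = 3.7e-06). The acute-phase genes Lcn2 and Saa3 fell by 1.56 and 2.40 and Il18, Tgfb1 and Cxcl10 by 0.79, 0.51 and 0.47, with Saa3 listed at 0 in hypoxia replicate 1. Cxcl10 did not pass without normal-pressure replicate 1 or 3 or hypoxia replicate 1 or 3, nor Tgfb1 without normal-pressure replicate 3. The median was -0.08 without normal-pressure replicate 1, -0.45 without normal-pressure replicate 2, -0.05 without normal-pressure replicate 3, where 3 fell, -0.16 without hypoxia replicate 1 and -0.11 with features above 0 in every library. With no filter 3 fell, the median was -0.07 and the camera adjusted p was 0.067 (0.000299 to 0.50 over the alternatives). Macrophage markers gave 2 rises and 2 falls among 16, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.35). Gpnmb and the lysozyme gene Lyz2 rose by 0.53 and 0.41, and Cx3cr1 and Fcgr1 fell by 0.41 and 0.42, with 5 falls under quantile, median-ratio and protein-coding total scaling and 0 with no filter, a minimum of 5 TPM or without normal-pressure replicate 1 or 3 or hypoxia replicate 1 or 2. The last 3 of these gene calls were each lost without 3 or more single libraries, and the list median changed sign without normal-pressure replicate 3 (0.04) or hypoxia replicate 1 (0.02) and was lowest with median-ratio scaling (-0.14).

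Besides haemoglobin and Insl3, the highest rises were in Bpifb4 (11.7 ± 3.53 to 46.1 ± 4.41 TPM), the secreted glycoprotein hormone gene Stc1 (12.1 ± 2.03 to 46.1 ± 9.08 TPM), Serpina3c (6.36 ± 0.526 to 22.2 ± 3.48 TPM), the fibrillar collagen gene Col11a1 (by 1.48 on the log2 scale, to 29.9 ± 4.09 TPM) and Bmp3 (6.38 ± 0.486 to 19.1 ± 2.51 TPM). Their limma adjusted p lay between 1.15e-06 and 2.28e-06. Besides the luteal genes, the steepest falls among protein-coding genes were in the homocysteine methyltransferase gene Bhmt (18.8 ± 1.23 to 1.97 ± 3.11 TPM), the Wnt ligand gene Wnt10b (52.3 ± 16.8 to 6.24 ± 4.43 TPM), Ccn5 (25.6 ± 12.1 to 2.34 ± 2.25 TPM), the calcium-binding protein gene S100a4 (74.3 ± 51.9 to 7.57 ± 2.21 TPM) and the lipase gene Lipg (64.4 ± 36.5 to 7.90 ± 3.74 TPM). Their adjusted p lay between 1.31e-05 and 0.000111. Bhmt and Wnt10b did not pass with robust variance. Among noncoding genes, the lncRNA Eldr rose from 4.39 ± 1.06 to 10.4 ± 2.06 TPM. Rnu1b1 and Rnu1b2, near-identical spliceosomal RNA genes with the same values in each library, rose by 0.75, an uncertain change because reads cannot be divided between them and because it did not pass without normal-pressure replicate 1 or with quantile, median-ratio or protein-coding total scaling, robust variance or no filter. Neat1 (chromosome 19, 5824708 to 5845480 in GRCm38.p6), the lncRNA scaffold of paraspeckles, fell from 441 ± 211 to 143 ± 42.2 TPM but did not pass with robust variance, and Mir22hg fell from 12.1 ± 1.62 to 6.94 ± 0.948 TPM. The small nucleolar RNA Snora43 (chromosome 2, 26637847 to 26637985) was listed at 0 in the 3 hypoxia libraries and at 187.7, 89.4 and 31.9 TPM in the normal-pressure libraries, and it did not reach the filter without any 1 of these 3.

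**Figure D2:**
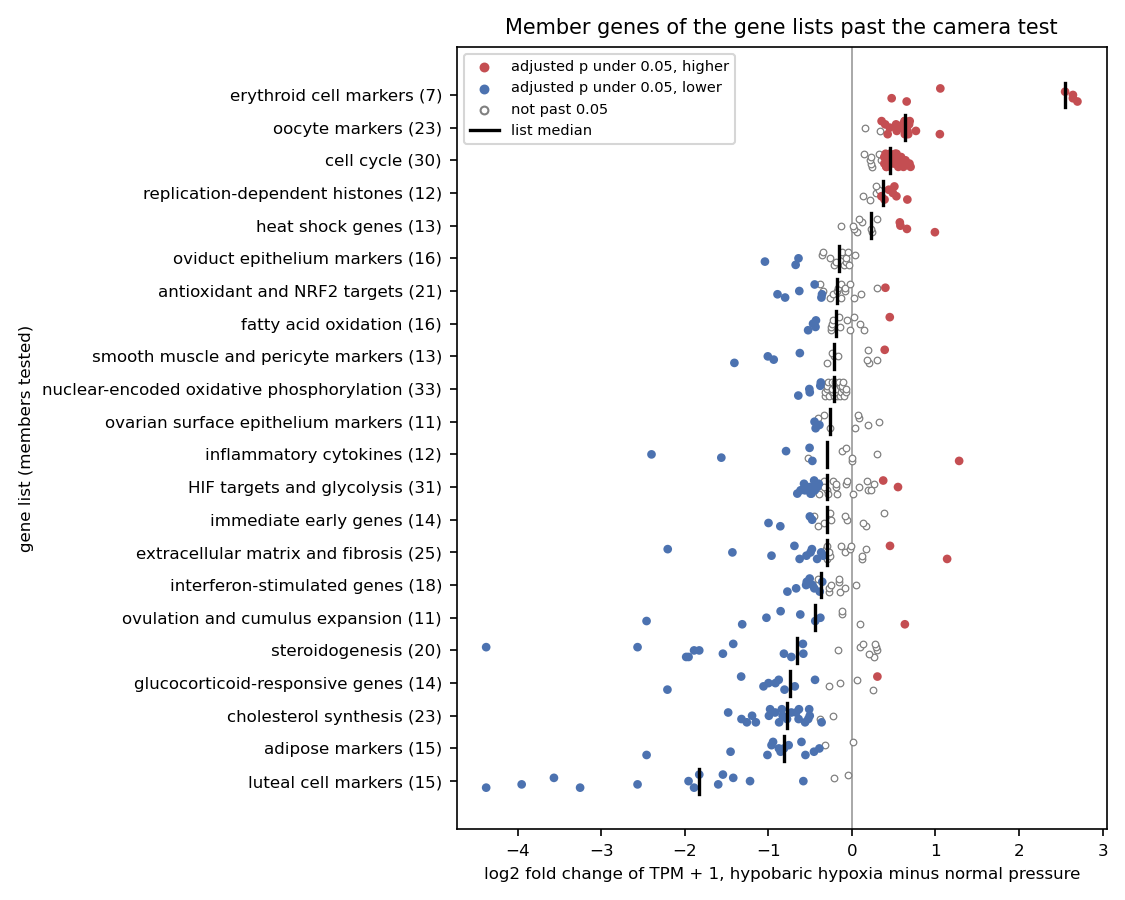
Log2 fold change of TPM + 1, hypobaric hypoxia minus normal pressure, for each tested member of the 22 lists past camera at its preset correlation, with filled points past an adjusted p of 0.05, open points not past it and list medians as bars. Medians run from -1.83 for luteal markers to 2.55 for erythroid markers, and most of the lower lists also hold members above 0.

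In all, camera called 22 of 32 lists, 5 higher and 17 lower. None of the 22 held with an estimated correlation, where 0 lists passed, and fry called only the erythroid list (adjusted p = 0.0234). Another split of the 6 libraries into 3 and 3 also gave 22 calls, with normal-pressure replicates 1 and 2 and hypoxia replicate 3 on one side. That split keeps part of the group difference, so it does not show how many lists would be called without one. With no filter on low values, 51 of the 147 named genes did not pass.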

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

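Scaling to the protein-coding total without Zfp949, protein-coding genes alone and features above 0 in every library were chosen after the data were seen. No called gene named here changed sign under any alternative, and no called list passed in the other direction, though the oviduct median was 0.01 without hypoxia replicate 2. With a pseudocount of 0.1, 512 genes changed at least 2-fold. With no filter on low values 1233 genes changed (687 higher and 546 lower), where more features were tested. Quantile normalization gave 6171 (3399 higher and 2772 lower), median-ratio scaling 5940 (3205 lower) and protein-coding total scaling 6289 (3756 higher and 2533 lower), and the cause was not tested. Leaving out 1 library gave 2065 to 3998 changed genes, 1170 to 2044 higher and 795 to 2143 lower, with fewer samples. Of 32 lists, 0 passed with an estimated correlation and 1 with fry, against 19 to 22 in the other settings. With the haemoglobin genes out, the erythroid list had too few members and gave no value. The replicate number as a block gave 4117 changed genes and 19 lists, which left out the ovarian surface epithelium, heat shock and fatty acid oxidation lists. Tsc22d3 did not pass with that block. Deviations of same-numbered libraries correlated at -0.034, 0.110 and -0.050 and of other pairs at up to 0.114, so not every library correlated best with its own number. Read depth is unknown, so its part in the calls of low genes was not assessed. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3139 changed genes (highest other 4), 1906 higher (2), 1233 lower (2), 306 at least 2-fold (4) and 5482 at unadjusted p under 0.05 (705), each a count that 1 of 10 splits reached, and 22 lists (22), a count that 2 of 10 reached.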

Other observations

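The tests in this part on luteal genes outside steroid synthesis and on oocyte genes against other cell types were chosen only after the results were seen. Replication-dependent histone genes rose in 7 of 12 members and none fell, and 10 rose when adjusted over the list alone (median 0.37, camera adjusted p = 0.000349, and adjusted p = 0.50 with an estimated correlation). H3c2, H3c1, H2ac4 and H4c9 rose by 0.66, 0.53, 0.49 and 0.44 on the log2 scale, and the count was 4 with median-ratio scaling, 3 without normal-pressure replicate 2 or hypoxia replicate 2, and 2 without normal-pressure replicate 1 or with no filter. H2ac4 did not pass without normal-pressure replicate 1 or hypoxia replicate 2, nor H4c9 without normal-pressure replicate 1 or 2. Among 16 circadian clock genes 5 rose and none fell, also when adjusted over the list alone (median 0.19, camera adjusted p = 0.21). Among them Hlf, Tef, Per3 and Per2 rose by 0.62, 0.39, 0.49 and 0.41, with 3 of the list past the test at a pseudocount of 0.1 or without normal-pressure replicate 2 or 3 or hypoxia replicate 1 or 2, 1 without hypoxia replicate 3 and 0 with no filter, and 2 other members fell with quantile or median-ratio scaling. The median was 0.08 without normal-pressure replicate 2 and 0.11 with median-ratio scaling. Among 30 annotated long noncoding RNAs 4 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone (median 0.08, camera adjusted p = 0.48). Epb41l4aos, Tug1, Dleu2 and the imprinted Meg3 rose by 0.45, 0.48, 0.36 and 0.36, beside the falls of Neat1 and Mir22hg. The rises numbered 8 with a minimum of 5 TPM or robust variance, 7 without normal-pressure replicate 1 and 0 without hypoxia replicate 2 or with no filter, and the median was -0.02 without normal-pressure replicate 2, -0.01 with median-ratio scaling and 0.17 without normal-pressure replicate 3.

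The unfolded protein and integrated stress response list had 1 fall among 18, also when adjusted over the list alone, in the glutathione-degrading enzyme gene Chac1 (-0.54), with a median of 0.04 but a mean of -0.02 and a camera adjusted p of 0.36 toward lower values. Chac1 did not pass without hypoxia replicate 2 and did not reach the filter without any 1 normal-pressure library or with a minimum of 5 TPM. No member fell without hypoxia replicate 2 or normal-pressure replicate 3, where 1 rose. The falls numbered 7, 5 and 4 with median-ratio, protein-coding total and quantile scaling and 3 with robust variance, protein-coding genes alone or without normal-pressure replicate 2, and the median ran from -0.06 with median-ratio scaling to 0.10 without normal-pressure replicate 3. Among 18 apoptosis and p53 targets 2 fell, also when adjusted over the list alone, the cell cycle inhibitor gene Cdkn1a from 19.98 ± 4.08 to 7.68 ± 3.43 TPM and Bak1 by 0.49, with a median of 0.08 but a mean of -0.05 and a camera adjusted p of 0.44 toward lower values. The falls numbered 5 with median-ratio scaling or without normal-pressure replicate 2 and 4 with quantile normalization, where 3 also rose, and the median ran from just below 0 with median-ratio scaling to 0.14 without normal-pressure replicate 3. Among 19 autophagy and mitophagy genes Bnip3 and Map1lc3a fell by 0.65 and 0.59 and Atg12 rose by 0.35, while 2 fell and none rose when adjusted over the list alone, with a median of 0.06 but a mean of -0.04 and a camera adjusted p of 0.19 toward lower values. The falls numbered 7 with median-ratio or protein-coding total scaling or without normal-pressure replicate 2 and 6 with quantile normalization, and the median was -0.05 without normal-pressure replicate 2 and -0.03 with median-ratio scaling. Atg12 was lost at a pseudocount of 0.1, with median-ratio scaling and without each of 4 single libraries. None of 50 cytosolic ribosomal protein genes passed, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.16), with Rpl9 at 0.24 on the log2 scale, and the list passed only with no filter, while 3 members rose with quantile normalization and 2 with protein-coding total scaling. The median was 0.05 without normal-pressure replicate 2 or with median-ratio scaling and 0.06 with quantile normalization. Skeletal muscle, lymphocyte, neutrophil and mitochondrially encoded genes had too few members above the filter for a list test. None of the members of smallest p passed, with Mylpf at -0.23, Jchain at -0.27, Lck at -0.16, S100a8 at -0.56 and Mmp9 at -0.18.

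The fall of luteal markers could come from less luteal tissue in the hypoxia libraries or from lower steroid synthesis in unchanged tissue. The 7 tested luteal markers outside steroid and cholesterol synthesis had a median log2 fold change of -1.60. They ran from -3.95 for Sfrp4 to -0.05 for Parm1, so the fall was not limited to steroid genes. Sfrp4, Ptgfr and Abcb1b were known to have fallen steeply when this test was chosen. The test therefore adds no independent support for less luteal tissue, which cannot be told apart here from a wider loss of luteal expression. Sfrp4, Ptgfr, Abcb1b, Prlr and Gpx3 passed and Timp3 and Parm1 did not. After scaling to the protein-coding total without Zfp949 the luteal median was -1.87, which met a bound set before the result was seen. That scaling moved the median of all tested features only from 0.08 to 0.05, so the bound could hardly have been missed. A shift of the total that small could not give the luteal fall, which speaks against scaling of this kind only. The cycle stage of each mouse is not in the labels, so a difference in the number or age of corpora lutea between groups was not tested. The labels give levonorgestrel and ethinylestradiol doses for the hypoxia samples only. If the controls were not dosed, hormone treatment cannot be told apart from hypoxia here.

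The rise of haemoglobin transcripts could come from more whole blood in the tissue. The erythroid markers Alas2 and Bpgm rose by 1.06 and 0.48, though Bpgm did not pass without hypoxia replicate 2 or with no filter. The neutrophil genes S100a8 (2.09 to 1.14 TPM) and S100a9 (1.25 to 0.447 TPM) had a mean log2 fold change of -0.54 (-0.536 before rounding), which met the bound set before against whole blood, but both lie so low that the question was left open after their values were seen. With libraries scaled to the protein-coding total the 4 haemoglobin genes had a mean log2 fold change of 2.60, against 2.64 in TPM as deposited. That scaling moved the median of all tested features only from 0.08 to 0.05, so it could hardly have removed the rise. A shift that small could not give the haemoglobin rise, which speaks against scaling of this kind only. Perfusion of the ovaries is not described in the labels.

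The rise of oocyte markers could follow from a smaller share of luteal tissue, in the simplest case with all other cell types raised alike. The oocyte median (0.63, 23 genes) lay 0.513 above the median of 77 pooled granulosa, theca, endothelial, smooth muscle and macrophage markers (0.12). Genes of the luteal and steroidogenesis lists were left out of that pool. The two-sided p was 7e-05 over 100000 permutations of genes. The oocyte rise was known when this test was chosen, so the test adds no independent evidence against a rise alike in all cell types. The permutation treats genes as independent, which genes of 1 cell type are not, so this p is too small. Luteal tissue can itself hold endothelial, smooth muscle and macrophage cells, whose markers would then be held down. A smaller luteal share that raises cell types unequally is therefore not excluded. After scaling to the protein-coding total the oocyte median was 0.596. That scaling moved the median of all tested features only from 0.08 to 0.05, so it could hardly have removed the rise. A shift that small could not give the oocyte rise, which speaks against scaling of this kind only. More oocytes per amount of tissue and higher expression per oocyte cannot be told apart here.

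Features with a mean of at least 10 TPM in the other 5 libraries but listed at 0 in 1 library numbered 0, 10 and 13 in normal-pressure replicates 1 to 3 and 28, 20 and 17 in hypoxia replicates 1 to 3, none of them protein coding and all of those with a known length under 300 bases. Snord15b, chosen after its values were seen, was listed at 0 in hypoxia replicate 1 and at 4342 to 5477 TPM in the other 5 libraries.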
